A study of Mus musculus with 8 samples.

How the data were processed

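Gene expression was measured in inguinal white adipose tissue (iWAT), the fat pad under the skin of the groin, in 4 samples from control mice and 4 from Senp2-aKO mice. Control mice carried Senp2 alleles flanked by loxP sites, and Senp2-aKO mice carried the same alleles with a Cre recombinase driven by the adiponectin gene, which is active in adipocytes. Per the labels, the mice were 8 weeks old when they began a diet with 58 kcal% fat, ate it for 12 weeks and lived at 22 to 24 °C. Total RNA was extracted with TRIzol, and 0.5 µg was labelled with Cy3 and hybridised to Agilent mouse arrays with 1 colour channel. The labels number the samples within each group and do not state that the numbers pair a control with a knockout mouse.

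Per the file headers and the submitters' processing notes, the scanner images were read with Agilent Feature Extraction 11.5.1, which finds spots, corrects the background for spatial trends, subtracts it and removes a multiplicative trend within the array. The deposited processed signal, median signal and median local background are intensity values, per the file headers, with no scaling between arrays. The deposited flags for signal above background, saturation and uneven spots are of the unit other, 0 or 1 per spot. The deposited matrix of normalised values was not used here, because its 8 sample columns carry names that match no label. Each array held 62976 spots, of which 3671 were controls, and up to 10 spots shared a probe.

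The log2 processed signal was taken relative to the 75th percentile of its array, and the spots of a probe were averaged without spots marked as outliers, which left out 269 probes of which no spot remained on some array. A probe was kept when it was well above background on at least 4 of the 8 arrays, whatever the group. Of 55681 probes, 27656 were matched through their RefSeq accession to 1 current gene name each (names from the RefSeq table of assembly GRCm38.p6) and 28025 had no name there. Of 30508 kept probes, 19231 were named, and the probe with the highest mean over the 8 arrays stood for its gene, which gave 14730 genes. Of these, 3761 had several kept probes. Among the 556 of them that passed the test, 9 had another probe that passed in the opposite direction, with adjustment over all 30508 kept probes.

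Both groups were compared with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), as a linear model with moderated variances. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are Senp2-aKO minus control, SE is their standard error, and fold intervals are 95% intervals. Single quantities were compared with an exact permutation test over all 70 assignments of 8 arrays into groups of 4, two-sided, whose smallest possible p is 0.0286. With 4 arrays in each group, the number of arrays limits the precision.

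The groups, the tests, the alternatives, 32 gene lists with 591 genes and the rule for naming genes were fixed before the data were examined. The lists cover brown and beige adipocytes, creatine and calcium cycling, the respiratory chain, the tricarboxylic acid cycle, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, branched chain amino acid catabolism, general adipocyte genes, C/EBP factors with their partners, the Hox C cluster, the SUMO pathway, lipolysis, insulin signalling, inflammatory cytokines, the interferon response, the extracellular matrix, the unfolded protein response, immediate early genes and the cell cycle. Marker lists cover macrophages, B and T lymphocytes, lymph node stroma, mammary epithelium, skin, skeletal muscle, endothelium, adipose progenitors, Schwann cells, red blood cells and sex-linked transcripts. Of the listed genes 7 were brought to a newer symbol, and 538 were measured. The 30 lists with at least 5 measured genes were tested with camera of limma at a preset correlation between genes of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry of limma were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Named genes were Senp2, 10 genes fixed in advance, the 10 largest rises and the 10 largest falls among genes that passed and whose groups did not overlap, and up to 4 genes of each list. This made 110 genes, some of which are not reported. A gene named outside this rule is said to be chosen after its values were seen.

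The test was checked on simulated arrays with changes placed in 50 genes at each size. Their values were drawn from normal distributions with each gene's control mean and spread. Genes were drawn independently, so the check does not cover correlated genes or an outlying array. It recovered 22% of the genes at a log2 change of 0.5, 68% at 1 and 98% at 2, and 17 of 160 calls were false (10.6%), which is above the nominal 5%. Alternatives were quantile normalisation, a background model on median signals (normexp of limma with an offset of 50), no filter on dim probes, a filter requiring signal on all 8 arrays, the mean of all probes of a gene, another variance prior, array weights, the replicate number as a block, the B lymphocyte list as a covariate, other thresholds, all probes as the unit, and leaving out each array. The skeletal muscle list as a covariate and the removal of genes that follow the muscle list were added after the data were seen. The background model was planned on mean signals, a column that the files do not hold, and was run on median signals.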

Results

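Expression profiles of iWAT on 8 arrays were compared between 4 samples from control mice and 4 from mice lacking Senp2 in adipocytes (Senp2-aKO), all fed a high-fat diet. Senp2 encodes a protease that removes the small protein SUMO from other proteins, and the series addresses whether its loss in adipocytes turns white fat towards a brown, heat-producing state through the transcription factor C/EBPβ.

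All 8 arrays lay on 1 slide and were read in 1 scan, with the control arrays in one row of the slide and the Senp2-aKO arrays in the other, so that slide row and group cannot be told apart. The 75th percentile of the signal was 419 ± 18.2 in controls and 349 ± 27.1 in Senp2-aKO samples (SD, n = 4 per group, exact permutation p = 0.0286). Probes well above background numbered 31058 ± 493 in controls and 30348 ± 700 in Senp2-aKO samples (SD, n = 4 per group, exact permutation p = 0.171). No spot was saturated. The correlation between arrays, across probes, which are not independent replicates, was 0.985 to 0.991 among controls, 0.964 to 0.990 among Senp2-aKO arrays and 0.943 to 0.977 between the groups. The first principal component carried 49.6% of the variance and separated the groups, and the second carried 21.9% and set aKO 2 apart. The Y-linked transcripts Ddx3y, Eif2s3y and Uty were above background on all 8 arrays, and Xist and the Y-linked Kdm5d on 0 of 8.

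Senp2 signal was 82.8% of control in Senp2-aKO fat (95% interval 73.3 to 93.6), with a mean log2 level of 2.45 ± 0.06 in controls and 2.18 ± 0.04 in Senp2-aKO samples (SD, n = 4 per group). All 4 Senp2-aKO arrays lay below all 4 controls (exact permutation p = 0.0286), while the limma test across all genes fell just short of its threshold (log2 fold change -0.27, SE 0.08, adjusted p = 0.0507). Senp2 was read by 1 probe, whose position relative to the removed exons is not stated, and the tissue holds cells other than adipocytes. Of 17 measured genes of the SUMO pathway 1 fell and 16 did not pass in limma. Adjusted over the list alone 0 of the 17 passed, with 4 lower at an unadjusted p under 0.05, and the list as a whole was not called (limma camera adjusted p = 0.567). The Senp2 test passed without aKO 2 (adjusted p = 0.0452).

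**Figure D1:**
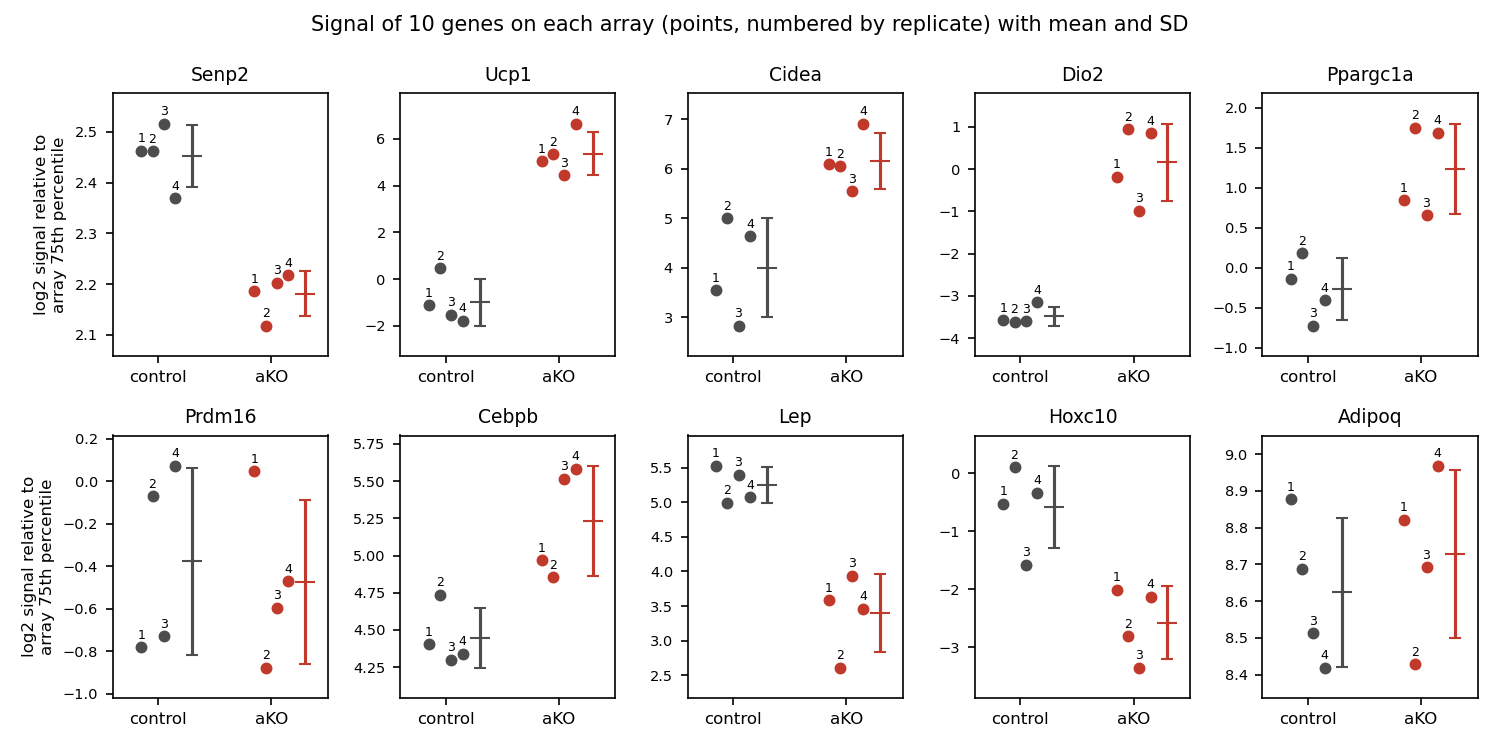
Log2 signal relative to the 75th percentile of the array (vertical axis, its range differing between panels) for 10 genes in 4 control and 4 Senp2-aKO samples, each point an array numbered by replicate, with the group mean and SD beside the points. The mean of Ucp1 was -0.99 in controls and 5.37 in Senp2-aKO samples, and that of Adipoq 8.62 and 8.73.

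Of 14730 genes tested, 1074 rose and 1049 fell in Senp2-aKO fat. A change of at least 2-fold was reached by 455 of the risen and 274 of the fallen genes, and one of at least 4-fold by 169 and 40. The largest rise was that of Trim63, a ubiquitin ligase of striated muscle (89.0-fold, 95% interval 30.1 to 263, n = 4 per group), followed by Ucp1, the uncoupling protein of brown fat (82.0-fold, 95% interval 32.0 to 210.2). Trim63 was above background on 2 of 4 control arrays, and its second probe gave a log2 fold change of 6.22 (SE 0.43), below the 6.36 of Ucp1, so that their order depends on the probe. Next came Ckmt2, Elovl3, Ckm, Tcap, Tnnt3, Sln, Fabp3 and Actn3, between 57.8-fold and 44.8-fold, and all of these except the fatty acid elongase Elovl3 are known transcripts of striated muscle. In 3871 genes (26.3%) the groups did not overlap, against 2.86% expected by chance, and 2065 of the 2123 genes that passed were among them. With the mean of the skeletal muscle list as a covariate, 1 gene rose and 0 fell in the limma test, with 959 higher and 735 lower at an unadjusted p under 0.05. That mean was higher on all 4 Senp2-aKO arrays than on any control, so the covariate widens the standard errors. These counts therefore do not show how much of the change muscle accounts for. Without the 144 genes that follow the muscle list, 1000 rose and 1032 fell. Removed were only genes whose deviations from the group means correlated above 0.8 with those of the muscle list. Muscle transcripts such as Myl1 and Sln stayed in, so these counts do not show what muscle accounts for either. The counts of 1074 and 1049 changed by more than 1.5 times on leaving out a control or aKO 1 or aKO 4. They were 436 higher and 280 lower without control 1, 687 and 500 without control 2, and 565 and 406 without control 3. They were 694 and 529 without control 4, 642 and 601 without aKO 1, and 628 and 531 without aKO 4.

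The largest falls were in genes of varied function. Car12, a membrane carbonic anhydrase, fell 12.5-fold (95% interval 5.47 to 28.4, limma adjusted p = 0.00668, n = 4 per group), and Tekt1, a tektin of cilia, 12.3-fold (95% interval 3.07 to 49.5, adjusted p = 0.0308). Gsg1l, an auxiliary subunit of glutamate receptors, was above background on 0 of 4 Senp2-aKO arrays and fell at least 4.52-fold. Oxtr, the oxytocin receptor, fell 9.0-fold (95% interval 3.72 to 21.8, adjusted p = 0.0124), and the kinase gene Dclk3 9.81-fold (95% interval 4.13 to 23.3, adjusted p = 0.0104). The remaining 5 of the 10 largest falls were the lysophosphatidic acid receptor Lpar3, the potassium channel Kcnj15, Plppr4, Ggt6 and Aadacl2fm1, with log2 fold changes from -2.86 to -2.46. A second probe of Plppr4 did not pass and gave -0.49 (SE 0.21, limma adjusted p = 0.180 over all kept probes). The Tekt1 call ended on leaving out any array but aKO 2 or aKO 3 (adjusted p from 0.0526 to 0.0823), that of Lpar3 any but aKO 3 (0.0554 to 0.104), and that of Aadacl2fm1 control 1 or control 3 (0.0524 to 0.0553).

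The series asks about browning, and genes of brown and beige adipocytes rose in Senp2-aKO fat. Ucp1, which lets mitochondria produce heat, had a log2 fold change of 6.36 (SE 0.59, limma adjusted p = 0.00329, n = 4 per group). Dio2, which activates thyroid hormone, rose 12.5-fold (log2 fold change 3.64, SE 0.41), and Elovl3 rose 52.0-fold (5.70, SE 0.66). Cidea, a lipid droplet protein, rose 4.43-fold (2.15, SE 0.49, adjusted p = 0.0267), and Ppargc1a, a coactivator of mitochondrial genes, 2.84-fold (1.51, SE 0.30, adjusted p = 0.0178). Cited1, a marker of beige adipocytes, rose 2.28-fold (1.19, SE 0.16), whereas Prdm16, a regulator of brown fat identity, did not pass (-0.10, SE 0.26, adjusted p = 0.827) and had a value above 0 under 5 of the alternatives.

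Of 32 measured brown and beige genes, 16 rose, 1 fell and 15 did not pass; adjusted over the list alone, 18 rose and 1 fell. The gene that fell, S100b, named after its value was seen, encodes a calcium-binding protein (log2 fold change -1.39, SE 0.35, limma adjusted p = 0.0356). The list had a median log2 fold change of 0.89 and a camera adjusted p of 1.23e-07, against an adjusted p = 0.610 with an estimated correlation and 0.0201 with fry of limma. Its mean was -0.04 ± 0.16 in controls and 1.36 ± 0.38 in Senp2-aKO samples (SD, n = 4 per group, exact permutation p = 0.0286). Fabp3, Cpt1b and, chosen after their values were seen, Cox7a1 and Cox8b (log2 fold changes 5.51, 2.14, 2.66 and 2.45) belong to this list and are known transcripts of muscle too. The skeletal muscle mean went from -0.38 ± 1.55 to 3.40 ± 0.52 on the same arrays. The Cidea call ended without control 1, control 3, aKO 1 or aKO 4 (adjusted p from 0.0535 to 0.0785) and that of Ppargc1a without control 1 (0.0509), and 9 genes of the list rose without control 1 and 10 without control 3. With the muscle mean as a covariate 0 genes of the list passed in the limma test, while the camera adjusted p was 1.41e-05.

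Transcripts of skeletal muscle rose in Senp2-aKO samples, 13 of 18 measured and 15 of 18 when adjusted over the list alone, with a median of 23.9-fold. Myh4, the myosin heavy chain of fast fibres, rose 39.9-fold (95% interval 11.2 to 142, limma adjusted p = 0.00774, n = 4 per group), and the fast light chain gene Mylpf 22.2-fold (7.49 to 65.6). The muscle enolase Eno3 rose 10.9-fold (5.54 to 21.6) and the light chain gene Myl1 5.13-fold (3.37 to 7.82). The 5 that did not pass, named after their values were seen, were the slow fibre genes Myh7, Tnni1 and Tnnt1 (log2 fold changes 0.89, 0.60 and 0.08) and the myosin genes Myh1 and Myh2 (2.74 and 2.49). The muscle list had a camera adjusted p of 7.54e-10, against an adjusted p = 0.610 with an estimated correlation and 0.0201 with fry of limma. Control arrays ranged widely, with list means of -1.72, -1.66, 1.33 and 0.54, and all 4 Senp2-aKO arrays lay above them at 2.72 to 3.96. Without control 1 the count of risen genes was 8, and Ckmt2, Ckm, Tnnt3 and Actn3 did not pass (adjusted p from 0.0508 to 0.0528); the Sln call held only without control 4 (0.0506 to 0.0828 in the other 7 omissions).

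Creatine and calcium cycling is a heat-producing route of adipocytes that does not need Ucp1 and shares genes with muscle. Of its 12 measured genes 4 rose, the calcium pump Atp2a1 (log2 fold change 4.06, SE 0.59, limma adjusted p = 0.00717, n = 4 per group), the calcium release channel Ryr1 (1.92, SE 0.33), Ckmt2 (5.85, SE 1.15) and Sln (5.54, SE 1.31). All 4 are abundant in skeletal muscle, whose list mean rose on the same arrays. Adjusted over the list alone, 4 rose and 1 fell. The list was not called (camera adjusted p = 0.417), and its median of -0.02 differed in sign from its mean of 1.21 and from the direction of the test. Without control 1 the Ckmt2 call ended (adjusted p = 0.0528), and that of Sln ended in every omission but that of control 4 (0.0506 to 0.0828).

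**Figure D2:**
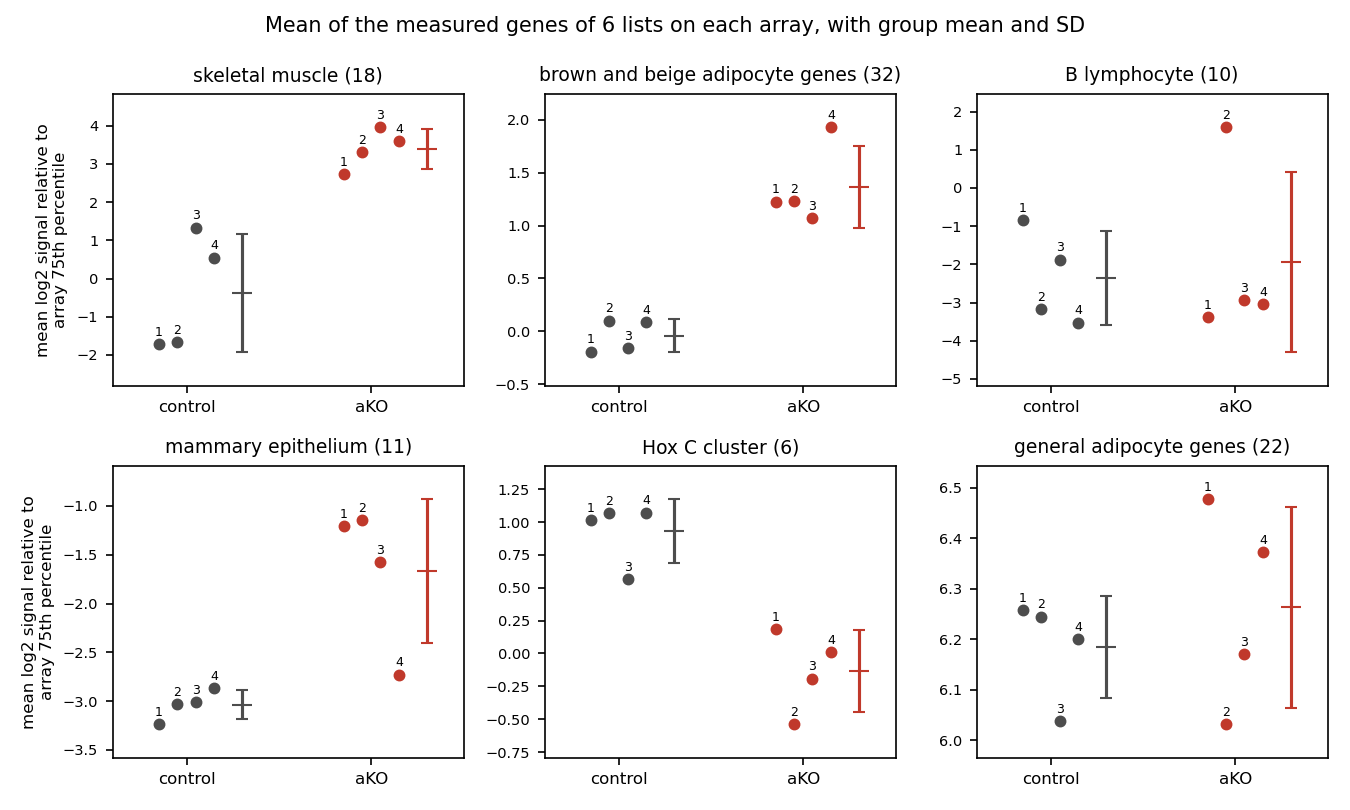
Mean log2 signal of the measured genes of 6 lists (vertical axis, relative to the 75th percentile of the array, its range differing between panels) on each control and Senp2-aKO array, with the group mean and SD beside the points. The skeletal muscle and brown fat means were higher on all 4 Senp2-aKO arrays, and the B lymphocyte mean of aKO 2 stood at 1.59 against -3.38 to -2.93 in the other 3.

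Genes of oxidative metabolism were slightly higher as groups. All 52 measured genes of the respiratory chain had positive log2 fold changes, from 0.11 to 0.60, and 5 rose. These were Cox7b of complex IV (0.53, SE 0.13, limma adjusted p = 0.0310, n = 4 per group), Uqcrb and Uqcrh of complex III (0.53 and 0.42), Sdhb of complex II (0.60) and Ndufb10 of complex I (0.41). Adjusted over the list alone 0 passed, with 26 higher at an unadjusted p under 0.05. The list was called by camera (adjusted p = 7.54e-10) but not with an estimated correlation (adjusted p = 0.904) nor by fry (adjusted p = 0.208). Its mean was 5.91 ± 0.14 in controls and 6.27 ± 0.27 in Senp2-aKO samples, and the groups overlapped (SD, n = 4 per group, exact permutation p = 0.0857). Skeletal muscle is rich in the same transcripts, and its list mean was higher on all 4 Senp2-aKO arrays, while the respiratory mean of aKO 2 (5.93) lay among the controls. However, aKO 2 also had the highest B and T lymphocyte means of all arrays (1.59 and 2.03), so its overlap does not part the respiratory genes from muscle. Of the first 4 genes, none passed on leaving out a control, aKO 1 or aKO 4 (adjusted p up to 0.115), whereas 32 of the 52 rose without aKO 2, 1 without aKO 3 and 0 in the other omissions. Under quantile normalisation 2 rose and the median log2 fold change was 0.20, against 0.36 as reported. The count of risen genes was 44 with array weights, 36 with the B lymphocyte mean as a covariate, and 0 with no filter on background or with the replicate block.

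Fatty acid oxidation, the tricarboxylic acid cycle and the breakdown of branched chain amino acids had median log2 fold changes of 0.37, 0.42 and 0.31 (limma camera adjusted p = 0.000177, 0.000223 and 0.000590; adjusted p = 0.904 for each with an estimated correlation). Under quantile normalisation the first median was 0.24, and without control 3 the third was 0.21. Cpt1b, which admits fatty acids to mitochondria, rose 4.41-fold (log2 fold change 2.14, SE 0.34, adjusted p = 0.00918, n = 4 per group), and Bckdhb, a subunit of the branched chain ketoacid dehydrogenase, 2.07-fold (1.05, SE 0.19, adjusted p = 0.0144). Of 25 genes of fatty acid oxidation 3 rose, the others being Acadvl and Eci1 (0.78 and 0.64); adjusted over the list alone 5 rose and 1 fell. In the tricarboxylic acid cycle 0 of 18 passed by either adjustment, that over all genes and that adjusted over the list alone, with 7 higher at an unadjusted p under 0.05 and Idh3b nearest (0.65, SE 0.18, adjusted p = 0.0507). Of 16 genes of branched chain breakdown 3 rose, Bckdhb and Hibch (1.05 and 0.59) among them, and 4 when adjusted over the list alone. The muscle list mean was higher on all 4 Senp2-aKO arrays, whereas these 3 list means overlapped the controls on aKO 2. Lymphocyte means were highest on aKO 2 (B 1.59, T 2.03), so the overlap does not part these lists from muscle. Cpt1b is the muscle form of its enzyme. Without aKO 2, 10 genes of fatty acid oxidation and 11 of the cycle rose, and without any control, aKO 1 or aKO 4, 1 of fatty acid oxidation and 0 of the cycle, except 1 without control 4. With array weights 19 and 15 rose, and with the B lymphocyte covariate 11 and 14. With no filter on background 1 and 0 rose. In the same omissions Hibch, Acadvl and Eci1 lost their calls (adjusted p from 0.0514 to 0.114), and 1 gene of branched chain breakdown rose without control 1, control 3, aKO 1 or aKO 4.

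**Figure D3:**
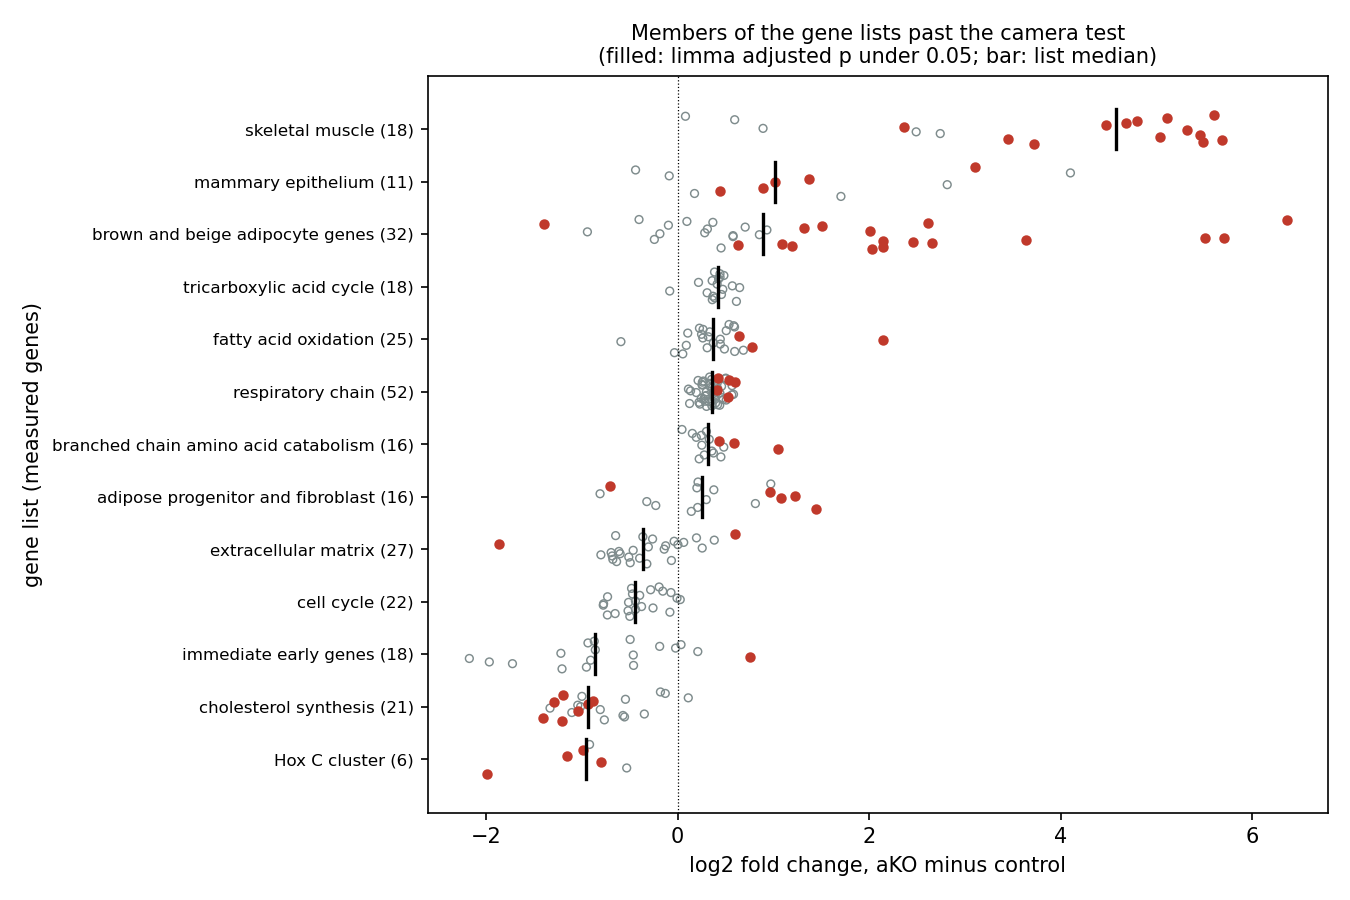
Log2 fold change, Senp2-aKO minus control (horizontal axis), of the measured genes of the 13 lists called by camera, each point a gene, filled where the limma adjusted p was under 0.05, with the list median as a bar and the number of genes beside the list name. The medians ran from 4.58 for skeletal muscle to -0.95 for the Hox C cluster.

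Genes of cholesterol synthesis fell. Dhcr7, which makes the last step to cholesterol, fell 2.65-fold (log2 fold change -1.41, SE 0.28, limma adjusted p = 0.0169, n = 4 per group), and Cyp51, a sterol demethylase, 2.30-fold (-1.20, SE 0.27, adjusted p = 0.0246). Of 21 genes 7 fell and 0 rose, and 11 fell when adjusted over the list alone. The median was -0.93 and the camera adjusted p 2.33e-05, against an adjusted p = 0.904 with an estimated correlation and 0.141 with fry. The list mean was 2.29 ± 0.09 in controls and 1.46 ± 0.56 in Senp2-aKO samples (SD, n = 4 per group, exact permutation p = 0.0286), with aKO 2 at 0.65 and the other 3 at 1.53 to 1.84. The muscle mean moved on the same arrays, and with it as a covariate the difference in list means was -1.10 (95% interval -2.77 to 0.57), against -0.82 without it (-1.52 to -0.12). With that covariate 0 genes of the list passed in limma (camera adjusted p = 1.41e-05). Counts of fallen genes were 0 without control 1, 3 without control 2, 1 without control 3, 2 without control 4 and without aKO 1, 5 without aKO 4, 10 without aKO 2 and 11 without aKO 3. Dhcr7 did not pass without control 1 (adjusted p = 0.0527), nor Cyp51 without control 1, control 3, control 4 or aKO 1 (0.0558 to 0.0738).

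Among general adipocyte genes, Lep, the satiety hormone leptin, fell 3.60-fold (95% interval 2.33 to 5.57, limma adjusted p = 0.00761, n = 4 per group), and Pnpla2, the main triglyceride lipase, rose (log2 fold change 0.52, SE 0.13). Adipoq, the hormone adiponectin, did not pass (0.10, SE 0.15, adjusted p = 0.665; -0.11 under quantile normalisation), nor did Pparg, the master regulator of adipocyte genes (-0.55, SE 0.18, adjusted p = 0.0717). Of 22 genes 1 rose and 1 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.288), with a median of 0.13 that turned to -0.10 under quantile normalisation. In fatty acid and triglyceride synthesis the phosphatidate phosphatase Lpin1 rose (0.91, SE 0.17, adjusted p = 0.0141) and Mid1ip1, an activator of acetyl-CoA carboxylase, fell (-0.88, SE 0.19, adjusted p = 0.0209). These were 1 each of 22, also when adjusted over the list alone (camera adjusted p = 0.811). Of the 22, 1 rose and 4 fell under quantile normalisation, 2 and 3 with the background model on median signals, 5 and 4 with array weights, 1 and 5 with the B lymphocyte covariate, and 2 and 4 without aKO 2. The median of -0.15 turned to 0.22 with array weights and without aKO 2. Lipolysis and adrenergic signalling had 3 risen and 1 fallen of 18 genes, 5 and 2 adjusted over the list alone (camera adjusted p = 0.417; median 0.03, -0.13 under quantile normalisation). G0s2, an inhibitor of Pnpla2, fell 2.97-fold (-1.57, SE 0.33, adjusted p = 0.0208). In insulin signalling 2 of 16 rose and 3 fell by both adjustments, that over all genes and that adjusted over the list alone (camera adjusted p = 0.963), among them Foxo1 (0.75) and Pik3r1 (-0.61). Pparg passed without aKO 2 (adjusted p = 0.0454). Calls ended for Pnpla2 without any control, aKO 1 or aKO 4, for Foxo1 without any array but aKO 3, and for Mid1ip1 without control 1, 2 or 3 or aKO 1. The same held for G0s2 without control 1, 2 or 3 and for Pik3r1 without control 1, control 2, aKO 1 or aKO 4 (adjusted p from 0.0505 to 0.0927 over these 5 genes).

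C/EBP factors start the adipocyte programme, and the series title names C/EBPβ. Cebpd rose 2.49-fold (95% interval 1.96 to 3.17, limma adjusted p = 0.00399, n = 4 per group) and Cebpb 1.72-fold (95% interval 1.27 to 2.35, adjusted p = 0.0332). Klf5, a partner in early adipocyte differentiation, rose (log2 fold change 0.91, SE 0.17), and Zfp423, a zinc finger protein that keeps adipocytes white, fell (-0.72, SE 0.19). Of 10 genes of this list 3 rose and 1 fell, and 3 rose and 2 fell when adjusted over the list alone. The list was not called (camera adjusted p = 0.670), and its median of -0.02 differed in sign from its mean of 0.15 and from the direction of the test. The Cebpb call ended without control 1, control 3, control 4, aKO 3 or aKO 4 (adjusted p from 0.0606 to 0.0892), that of Klf5 without control 1 (0.0507) and that of Zfp423 without any control, aKO 1 or aKO 4 (0.0645 to 0.108). With no filter on dim probes the Cebpb adjusted p was 0.0550, and with the replicate number as a block 0.0923.

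Homeobox genes of the Hox C cluster, which mark position along the body axis, fell in Senp2-aKO fat. Hoxc10, reported to restrain browning of subcutaneous fat, fell 3.98-fold (95% interval 2.06 to 7.68, limma adjusted p = 0.0197, n = 4 per group), and Hoxc6 2.23-fold (1.64 to 3.04, adjusted p = 0.0108). Hoxc8 fell 1.98-fold (1.49 to 2.64, adjusted p = 0.0137) and Hoxc5 1.74-fold (1.30 to 2.33, adjusted p = 0.0257). These were 4 of 6 measured genes, and 5 fell when adjusted over the list alone. The list mean was 0.93 ± 0.24 in controls and -0.13 ± 0.31 in Senp2-aKO samples (SD, n = 4 per group, exact permutation p = 0.0286). Camera called the list (adjusted p = 0.000735), as did fry (adjusted p = 0.0201), against an adjusted p = 0.610 with an estimated correlation. The Hoxc10 call ended without control 1 or control 4 (adjusted p = 0.0595 and 0.0521) and that of Hoxc5 without any control, aKO 1 or aKO 4 (0.0509 to 0.0713), so that 2 genes fell without control 1 or control 4. The muscle mean was higher on the same Senp2-aKO arrays, and with it as a covariate the difference in list means was -0.62 (95% interval -1.64 to 0.41), against -1.07 without it (-1.55 to -0.58).

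Markers of mammary epithelium rose in 5 of 11 measured genes, and in 8 when adjusted over the list alone. The list held 19 genes. Ddx3y, Eif2s3y and Uty, which are Y-linked, were above background on all 8 arrays and Xist on 0, and the source of the epithelial transcripts was not tested. Krt5 and Krt14, keratins of basal epithelial cells, rose 2.58-fold (95% interval 1.89 to 3.54, limma adjusted p = 0.00703) and 1.86-fold (1.51 to 2.30, adjusted p = 0.00761), each with n = 4 per group. Wfdc18, a secreted epithelial protein, rose 8.60-fold (2.27 to 32.7, adjusted p = 0.0441), and Krt19 2.02-fold (1.32 to 3.08). The camera adjusted p was 0.000698 and that of fry 0.0201, against an adjusted p = 0.610 with an estimated correlation. The list mean was -3.04 ± 0.15 in controls and -1.21, -1.14, -1.58 and -2.73 on the 4 Senp2-aKO arrays. The Wfdc18 call held only without aKO 4 and that of Krt19 only without control 4 or aKO 4 (adjusted p from 0.0580 to 0.106 in the other omissions). Genes of the list that rose were 2 without control 1, 2 or 3, aKO 1 or aKO 3, and 3 without aKO 2. With the replicate block 2 rose. The muscle mean was higher on all 4 Senp2-aKO arrays too, and with it as a covariate the list mean differed by 1.40 (95% interval -0.85 to 3.65), against 1.37 without it (0.45 to 2.29).

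Stromal genes passed in both directions, in numbers that depended on the setting. Among markers of adipose progenitors and fibroblasts Ly6a, a surface antigen of stem cells, rose 1.95-fold (log2 fold change 0.97, SE 0.12, limma adjusted p = 0.00510, n = 4 per group), and Dlk1, an inhibitor of adipocyte differentiation, 2.12-fold (1.08, SE 0.17). Dpp4, a marker of early progenitors, rose 2.34-fold (1.23, SE 0.20), while Pdgfrb, a receptor of mural cells, fell 1.63-fold (-0.71, SE 0.13). Of 16 genes 4 rose and 1 fell, and 6 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0166; adjusted p = 0.904 with an estimated correlation). Of 27 genes of the extracellular matrix, Timp3, an inhibitor of matrix proteases, rose (0.60, SE 0.11, adjusted p = 0.0139) and Mmp12, a macrophage elastase, fell (-1.86, SE 0.51, adjusted p = 0.0475), and adjusted over the list alone 1 rose. At an unadjusted p under 0.05, 2 matrix genes were higher and 9 lower. With 1 risen in each of these settings, 4 matrix genes fell under quantile normalisation or with the B lymphocyte covariate, 3 with the trended prior or without aKO 2, 6 with array weights, and 0 with signal on all 8 arrays, no filter on background or the replicate block. The matrix list had a median of -0.36 (camera adjusted p = 0.0447; adjusted p = 0.904 with an estimated correlation). The progenitor call ended without aKO 3 (adjusted p = 0.16), where 3 of its genes rose and 3 fell, and the matrix call without control 3, control 4 or aKO 2 (0.078, 0.055 and 0.11; median -0.22 without aKO 2). The progenitor call also ended with the background model on median signals, no filter on background or the muscle covariate (camera adjusted p = 0.0502, 0.0739 and 0.650). The matrix call ended with signal on all 8 arrays, array weights or the B lymphocyte covariate (0.0709, 0.0691 and 0.0516). Mmp12 was above background on 1 of 4 Senp2-aKO arrays and passed only without control 2 or aKO 4 (0.0687 to 0.120 in the other omissions).

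Genes of cell division and of the immediate early response were lower as groups, with few or no members past the test. In the cell cycle list 0 of 22 passed by either adjustment, that over all genes and that adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. The mitotic kinase Aurka came nearest (log2 fold change -0.50, SE 0.14, limma adjusted p = 0.0541). Its median was -0.44, and -0.23 with the background model on median signals and -0.26 without aKO 1 (camera adjusted p = 0.0133; adjusted p = 0.904 with an estimated correlation). Of 18 immediate early genes Fosl2 rose (0.76, SE 0.19, adjusted p = 0.0337), whereas 1 rose and 6 fell when adjusted over the list alone. The median was -0.87 (camera adjusted p = 0.0258; adjusted p = 0.904 with an estimated correlation), and Egr2 had a value of -1.97 (SE 0.55, adjusted p = 0.0503). The cell cycle call ended without control 3 or aKO 1 (0.074 and 0.11), and 4 of its genes fell without aKO 2 and 5 with array weights. The immediate early call ended without control 2, control 3, aKO 1 or aKO 2 (0.068 to 0.12), while 5 of its genes fell without aKO 3 and 3 without control 4. It also ended with array weights, the B lymphocyte covariate or the muscle covariate (camera adjusted p = 0.0655, 0.0621 and 0.107). Under quantile normalisation, the background model, signal on all 8 arrays or the trended prior, 4 of its genes fell in each. Fosl2 passed only without control 2 or aKO 1 (0.0518 to 0.0909 in the other omissions). In the unfolded protein response 4 of 16 rose, among them Chac1, a glutathione-degrading enzyme (1.38, SE 0.36), and 1 fell, Trib3, a pseudokinase (-1.04, SE 0.20); adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.121). The count of risen genes was 1 under quantile normalisation, with the replicate block or without aKO 1, 4 without aKO 2, and 0 with no filter on background or in the other 6 omissions (5 higher at an unadjusted p under 0.05 in limma). Trib3 did not pass without control 1 (adjusted p = 0.0550), nor Chac1 without any array but aKO 2 (0.0616 to 0.0965).

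Immune cell markers were not called as groups. Ccr2, the chemokine receptor of recruited monocytes, fell 2.65-fold (95% interval 1.93 to 3.64, limma adjusted p = 0.00660, n = 4 per group), while Cd163 and Clec10a, receptors of resident macrophages, rose 2.05-fold and 1.75-fold (adjusted p = 0.0192 and 0.0325). Of 20 macrophage genes 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.806), with a median of -0.01 and a mean of -0.14 against an upward test. Of 23 inflammatory genes 3 fell, Nos2, Ccl2 and Ccl4 (log2 fold changes -1.30, -2.13 and -1.63), and Lcn2 rose (1.41), as also when adjusted over the list alone (camera adjusted p = 0.342). Among 19 interferon response genes Irf7 rose and Ifit3 and Cmpk2 fell (0.65, -0.65 and -0.68). When adjusted over the list alone, 3 rose and 3 fell (camera adjusted p = 0.881, median -0.06 and mean 0.04). Of the 19 genes, 5 follow the muscle list. With the muscle mean as a covariate the interferon mean differed by -0.46 (95% interval -0.86 to -0.07), against 0.04 without it (-0.27 to 0.35). That covariate separates the groups, and the interval was not corrected for the number of lists, so it does not show a fall. In the T and B lymphocyte lists 0 of 16 and 0 of 10 genes passed in limma, also when adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.288 and 0.60). Both list means were highest on aKO 2. Without control 1 the Cd163 call ended (adjusted p = 0.0615). Each of Clec10a, Nos2, Ccl2, Ccl4, Lcn2, Ifit3, Irf7 and Cmpk2 lost its call in 4 to 7 of the 8 omissions, aKO 1 among them for every one (adjusted p from 0.0506 to 0.120).

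Of 15 endothelial markers Sox17, a transcription factor of arteries, rose (log2 fold change 1.18, SE 0.26, limma adjusted p = 0.0245), also when adjusted over the list alone (camera adjusted p = 0.660; median -0.03 and mean 0.07). Of the 4 measured lymph node stroma genes, too few for a list test, Lyve1, a receptor of lymphatic vessels, rose 3.36-fold (95% interval 1.96 to 5.74, adjusted p = 0.0158, n = 4 per group). None of 6 skin, 12 Schwann cell or 7 red blood cell genes passed over all genes in limma, with 3, 4 and 0 of them at an unadjusted p under 0.05 (camera adjusted p = 0.956, 0.956 and 0.429). Adjusted over the list alone, 1 skin gene rose and 2 fell, and 0 of the Schwann cell and red blood cell genes passed. The Schwann list had a median of 0.04 and a mean of -0.12, and the skin list 0.14 and -0.03, with upward tests for both. Sox17 did not pass without control 1, control 3, control 4 or aKO 4 (adjusted p from 0.0501 to 0.0673), nor Lyve1 without control 1 (0.0524).

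Other counts moved with the processing too. Over quantile normalisation, the background model, the filters, the mean of probes, the trended prior, array weights, the replicate block and the B lymphocyte covariate, risen genes numbered 13 to 19 for brown and beige adipocytes and 12 to 14 for skeletal muscle. They numbered 2 to 4 for creatine and calcium cycling (0 to 2 fell) and 1 to 7 for branched chain breakdown, while 4 Hox C genes fell in each. Risen and fallen genes numbered 0 to 3 and 1 to 2 for general adipocyte genes, 2 to 6 and 1 to 3 for lipolysis, 0 to 3 and 0 to 3 for insulin signalling, and 1 to 3 and 0 to 2 for C/EBP factors. For macrophages they numbered 1 to 3 each, for inflammatory genes 0 to 2 and 1 to 4, and for the interferon response 0 to 2 and 1 to 3. Fallen genes numbered 5 to 12 for cholesterol synthesis and 0 to 3 for the SUMO pathway and for Schwann cells. With array weights the median turned from 0.48 to -0.65 for B lymphocytes and from 0.51 to -0.36 for T lymphocytes. With the muscle mean as a covariate 0 genes of any list passed in limma, against 959 higher and 735 lower of all genes at an unadjusted p under 0.05. That covariate separates the groups, which widens the standard errors.

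Of the 30 lists tested, 13 were called by camera of limma at the preset correlation. With an estimated correlation 0 were called, and fry called 4: brown and beige adipocytes, skeletal muscle, mammary epithelium and the Hox C cluster. Of the 110 named genes 90 passed over all genes, and 36 of these passed whichever single array was left out, among them Ucp1, Dio2, Elovl3, Lep, Cebpd, Hoxc6, Hoxc8, Myh4 and Trim63. Other kept probes did not pass for Plppr4, Lpin1, Foxo1, Zfp423, Cmpk2, Sdhb, Uqcrb, Uqcrh, Gsk3b and Atf4, although the reported ones did (limma adjusted p from 0.0533 to 0.180). The other probes were adjusted over all 30508 kept probes, the reported ones over 14730 genes. A value just above 0.05 therefore need not mean that the probes disagree. The log2 fold change of the other Uqcrh probe was 0.43 (SE 0.12), against 0.42 (SE 0.11) for the reported one.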

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

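The tests of muscle tissue, of muscle genes moving with Ucp1, of brown genes with the muscle covariate and of the Hox C genes were chosen after the results were seen, while those of the respiratory chain were written before their results were seen. A sample was picked out when its gap to the nearest of its group was large against the range of the group, which chance does in about 5% of groups and here happened in 12 of 284. Signals below are log2 values relative to the 75th percentile of the array.

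Skeletal muscle transcripts were 23.9-fold higher at the median in Senp2-aKO samples, and muscle left on some of the dissected pads may account for it. Within groups the muscle genes rose and fell together. The median pairwise correlation of their deviations from the group means was 0.886, against 0.272 at the upper end of the central 95% of random lists. Muscle tissue in the samples would give this, but so would any genes regulated together, so the correlation cannot tell these apart. The within-group relation to Ucp1 predicts 4.81% of the Senp2-aKO mean (95% interval -56.2 to 65.8), against a measured difference of 81.9%. Ucp1 was at 0.596% to 2.81% of its Senp2-aKO mean in controls, so the slope rests mainly on the Senp2-aKO arrays. The error of the measured difference was left out. The test therefore argues only weakly against muscle genes made in step with the brown fat programme. Whether muscle was left on more often by chance, by the order of dissection or because of the genotype was not tested, and slide row is confounded with genotype. The muscle level was 10.2% to 32.9% of the Senp2-aKO mean in controls and 56.0% to 143% in Senp2-aKO samples.

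Brown fat genes were higher on all 4 Senp2-aKO arrays, as the muscle genes were, and the respiratory chain mean on 3 of them but not on aKO 2, so muscle RNA could have raised them. With the muscle list mean as a covariate, the brown and beige list mean differed by 1.41 (95% interval 0.16 to 2.65), against 1.40 without it (0.89 to 1.91). The difference thus did not shrink with this covariate. However, the covariate separates the groups and was fitted on log2 means, whereas RNA of added tissue adds to the unlogged signal. The result therefore does not decide whether muscle was the cause. An earlier test on within-group slopes of unlogged signals gave 4.97% (-67.6 to 77.6) against a difference of 36.2% and decided nothing. Single genes lost their calls with the covariate: Ucp1 went from a log2 fold change of 6.36 (SE 0.59) to 7.95 (SE 1.16, limma adjusted p = 0.277), where the standard error widened, and Fabp3 from 5.51 (SE 0.85) to 1.31 (SE 0.77, adjusted p = 0.549), where the fold shrank. For the respiratory chain, the within-group relation to muscle predicts a difference of -7.68% of the Senp2-aKO mean (95% interval -53.6 to 38.2) and that to Ucp1 13.3% (-13.0 to 39.6), against a measured 22.8%, so that with 8 arrays neither source can be excluded. The genotype remains an open and untested explanation for both lists.

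Hox C genes were lower in Senp2-aKO samples, and dilution by RNA of another tissue or fat taken from another position along the body are candidate explanations. Dilution would lower adipocyte genes alike, but the median log2 fold change of the general adipocyte list was 0.13, above every Hox C gene (-1.99 to -0.53). Its 95% interval (-0.07 to 0.30) came from resampling the genes of the list, not the arrays. Between arrays the mean of that list differed by 0.08 (95% interval -0.20 to 0.35). These values argue against dilution as the whole cause. Under quantile normalisation the adipocyte median was -0.10. A shift in position would be likely to grade the change by paralogue number in the other clusters, and across 20 genes of clusters A, B and D, which are not independent replicates, the Spearman rho was -0.0771 (95% interval -0.526 to 0.387, permutation p = 0.745), so that position stays open. With the muscle list mean as a covariate the Hox C mean differed by -0.62 (95% interval -1.64 to 0.41), against -1.07 (-1.55 to -0.58) without it. An effect of the genotype was not tested apart from slide row and dissection.

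Dio2 in control 4 was at -3.145, above the other controls at -3.608 to -3.575. Sln in control 4 was at -1.138, above the others at -7.149 to -6.423. Gsg1l in aKO 3 was at -4.943, above the others at -6.613 to -6.338. Hoxc6 in control 3 was at 2.911, below the others at 3.145 to 3.151, and the Hox C mean of that array was 0.568, below the others at 1.01 to 1.07. On aKO 2, Fcrla, a B cell gene, was at 0.701 and Tcf7, a T cell gene, at 0.157, against highest values of -3.706 and -4.146 on the other Senp2-aKO arrays, and the B lymphocyte mean was 1.59 against -3.38 to -2.93. The haemoglobin gene Hbb-b1 on aKO 2 was at 4.901 against 3.546 to 3.733, and the red blood cell mean at 5.77 against 4.43 to 4.60. The Schwann cell and nerve mean of control 4 was -0.135, below the others at 0.02 to 0.04. The 75th percentile of the signal of control 3 was an intensity of 445.911, above the others at 408 to 411. Among 11277 kept probes without a gene name, which the comparison of named genes did not use, 554 were higher in Senp2-aKO samples than in controls and 274 lower at an adjusted p under 0.05 in limma.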

How the results depend on the processing

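The muscle covariate, the removal of the 144 genes that follow muscle and the background model on median signals were chosen after the data were seen; the rest was planned. The planned run on the deposited normalised matrix was not run, since its columns match no sample, nor was a second Senp2 probe, since the arrays hold 1. The counts of genes, 1074 higher and 1049 lower, became 1831 and 1932 with array weights (aKO 2 had the lowest weight, 0.17), 1624 and 1897 at an adjusted p under 0.10, which the wider threshold explains, and 1 and 0 with the muscle covariate (959 and 735 at an unadjusted p under 0.05; limma). The muscle covariate separates the groups and so widens the standard errors, and its counts do not measure what muscle accounts for. All kept probes gave 1673 higher. The lower count was 689 with no filter on background, 569 with the replicate block and 1705 with the B lymphocyte covariate. Leaving out 1 array gave 436 (without control 1) to 1353 (without aKO 2) higher and 280 to 1472 lower, from the same arrays. Other settings kept the counts within 1.5 times, with 1000 higher and 1032 lower without the genes that follow muscle and 1037 and 1443 under quantile normalisation. The cause of the other shifts was not tested.

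The Senp2 log2 fold change stayed between -0.31 and -0.25 and passed with quantile normalisation (-0.27), the background model on median signals (-0.31), signal on all 8 arrays (-0.27), the trended robust prior (-0.27), array weights (-0.25) and the B lymphocyte covariate (-0.27), with limma adjusted p from 0.0162 to 0.0473. Leaving out 1 array gave -0.30 to -0.25, and it passed without aKO 2 (adjusted p = 0.0452). The cause was not tested. The brown and beige list lost its call only with an estimated correlation (camera adjusted p = 0.610); fry gave 0.0201, and camera from 2.40e-08 to 1.41e-05 in the other settings. Lists called were 0 with an estimated correlation, which allows for correlated genes, 4 with fry, and 10 to 14 in every other setting.

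Some named genes changed sign, and the cause was not tested unless given. Prdm16 was 0.0459 with array weights, 0.10 with the muscle covariate, and -0.27 to 0.0534 over the omissions (above 0 without control 2, control 4 or aKO 2). Adipoq was -0.11 under quantile normalisation. With the muscle covariate, built from such genes, Ckmt2 was -0.17, Ckm -0.34, Tnnt3 -0.47 and Actn3 -0.26. Over the omissions Cd79a ranged from -0.13 to 1.05, Fcrla from -0.33 to 1.42 and Tcf7 from -0.00146 to 1.6, each lowest without aKO 2, the array that was highest for lymphocyte markers, and Fcrla was -0.18 with array weights. Uty was 0.30 with the background model, 0.14 with the mean of all probes, 0.0397 with the muscle covariate, and -0.22 to 0.42 over the omissions.

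The replicate numbers in the labels gave little sign of pairing, although a pairing that leaves a weak trace cannot be excluded. Deviations from the group mean correlated at -0.02, -0.08, 0.14 and 0.11 for equal numbers, across genes. Only for number 3 was the equal number the closest match. With the replicate block 725 genes were higher and 569 lower. The replicate number equals the slide column of the array, so this block is also one of slide column. Over all settings 1576 results for named genes kept direction and call, 415 lost the call, 36 gained one and 20 changed sign. Signal over background limits Trim63, Ckmt2, Car12 and Lpar3, which were above background on 2 of 4 arrays of their lower group, Sln, Mylpf and Mmp12, on 1 of 4, and Gsg1l, on 0 of 4.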

Other observations

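The counts over other splits of the arrays were planned, while the 8 further gene lists described next were chosen after the data were seen. A test of such a list as a group would run on genes picked for what had been seen, so none is given.

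Known targets of the glucocorticoid receptor rose in Senp2-aKO fat, 9 of 12 measured genes, with a median of 2.37-fold. Fkbp5, a chaperone that restrains the receptor, rose 5.76-fold (log2 fold change 2.53, SE 0.35, limma adjusted p = 0.00639, n = 4 per group), and Pdk4, which limits the entry of pyruvate into mitochondria, 4.62-fold (2.21, SE 0.23, adjusted p = 0.00367). The metallothionein genes Mt2 and Mt1 (1.62 and 1.18), Zbtb16 (1.31), Klf9 (0.77), Tsc22d3 (0.55), Cebpd and Lcn2 rose too, while Per1, Sgk1 and Saa3 did not pass (0.17, 0.16 and -1.80). Cebpd and Lcn2 also belong to lists fixed in advance. Pdk4 is abundant in skeletal muscle too, whose list mean was higher on the same arrays. The list mean was 4.30 ± 0.17 in controls and 5.25 ± 0.10 in Senp2-aKO samples (SD, n = 4 per group).

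Of 18 glycolysis genes 4 rose, Eno3 and Pgam2, both muscle forms, Pfkm and Aldoc (log2 fold changes 3.45, 5.43, 1.22 and 1.80), on arrays where the muscle list mean was higher. Of 6 lymphatic vessel genes Lyve1 and Pdpn rose (1.75 and 0.84), and the list mean was 1.69 on aKO 2 against 0.24 to 0.42 on the other Senp2-aKO arrays. In the Hox B cluster Hoxb5 and Hoxb3 fell, 2 of 8 (-1.16 and -0.93), and in the Hox A cluster Hoxa10 fell (-1.58), 1 of 9. Among secreted factors of adipocytes Sfrp5 and Lep fell and Nampt rose (-1.22, -1.85 and 0.83). Of 17 circadian clock genes Ciart and Cry2 rose (1.67 and 0.32), and of 23 proteasome genes 0 passed in limma, with 1 at an unadjusted p under 0.05.

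For the number of genes that passed, the real split of the 8 arrays gave 2123 and the highest of the others 1. Only 1 of 35 splits, the real one, reached the count, which is the lowest share that 35 splits allow. Every other split mixes the groups, so a large group difference of any source lowers its calls. The rank therefore does not exclude chance, and the margin does not measure it. For the brown and beige list the real split also had the smallest camera p of the 35, 1.23e-08 against 7.13e-08 in the lowest of the others. With so narrow a margin the rank does not exclude chance. That camera p rests on a preset correlation of genes, and with an estimated one the list was not called (adjusted p = 0.610). Chance cannot be excluded for the number of lists called: 12 of 35 splits called as many as the 13 of the real split, and the highest of the others called 17.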
